A study of Homo sapiens with 9 samples.

How the data were processed

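Transcripts were measured by RNA-seq in 9 libraries of MOLM-13 cells with inducible Cas9, 3 each of the control, KO-1 and KO-2. Groups and replicate numbers were taken from the sample titles, and the genotype labels give control or MPP8 knockout. Per the labels' protocols, cells grew in RPMI-1640 medium with serum, and libraries were made from total RNA with a directional NEBNext Ultra II kit and sequenced on a NextSeq500. Whether poly(A) selection or removal of ribosomal RNA was used is not given in the sources used here. Per the submitters' processing notes, STAR, featureCounts, DESeq2 and the hg38 build were used, with no versions, and the roles of the tools were not stated. The values deposited by the authors are whole-number counts per feature, without normalization. Each file holds 76218 features, of which 60609 are genes and 15609 are repeats (14218 simple repeats and 1391 others). The strand setting of the counting and the treatment of reads that map to several places are not given in the sources used here.

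Gene counts per library were 14770649, 14867377 and 16567775 in the control, 14982362, 15120067 and 10531040 in KO-1, and 14945617, 14931647 and 13361977 in KO-2. Gene symbols were matched by identifier without version for 60340 genes, and GENCODE 29 models on GRCh38 gave exons, positions and classes for 58457. The exact version matched for 41747 genes, so exon numbers of the others may come from another version of the model.

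Genes were filtered with filterByExpr of edgeR 4.0.16 in R 4.3.3 and scaled with TMM factors. A quasi-likelihood negative binomial model with 1 mean per group and 6 residual degrees of freedom was fitted with glmQLFit and tested with glmQLFTest. Contrasts were the average of the KO groups against the control, each KO group against the control, and KO-2 against KO-1. Values of p were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Standard errors were derived from the F statistics. Levels are CPM on TMM-scaled library sizes, with the SD of 3 libraries, and log CPM used a prior count of 2. The model, filter, contrasts, gene lists, named-gene rule and most alternatives were fixed before the data were examined.

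Gene lists were written from general knowledge, 33 in all, of which 31 had at least 5 tested genes. They were tested with camera of limma 3.58.1 at a preset correlation of 0.01, with an estimated correlation and with fry as alternatives. Classes of genes were compared with Fisher's exact two-sided test, adjusted over all class tests. Correlation between the KO groups was set against 100 simulated pairs of unchanged groups with the same controls, and a further 10 were refitted and gave 0 calls in edgeR. The pairs were drawn around the mean of those control libraries, which leaves out the sampling error of the controls. They therefore cannot show how much correlation or overlap shared controls give.

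The genes named in the text were chosen by rule. They are MPHOSPH8 and measured HUSH partners, and the 10 raised and 10 lowered genes with the largest log2 fold change in the KO average. These had to be called in both KO groups in the same direction, with an average log CPM of at least 1, a symbol that is not a clone or locus name, and every KO library on the same side of every control library. For KO-2 against KO-1 the 5 highest and 5 lowest genes without overlap of libraries were named. For each list called in the KO average, and for 8 lists chosen in advance, the 3 members with the smallest p were named. The rule named 85 genes. Names outside it are transposable elements, members of the follow-up lists, and the mitochondrial genes MT-TG, MT-RNR1 and MT-RNR2, all chosen after their values were seen.

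The analysis of repeats was chosen after seeing the data. Repeats other than simple repeats were filtered and tested with the same model, using the gene counts as library size and the TMM factors of the genes, and 989 of 1391 passed. Factors taken from the repeats themselves were an alternative. The test against a 1.5-fold change (glmTreat) and the removal of processed pseudogenes were also chosen after seeing the data.

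Alternatives mostly changed 1 choice at a time, but DESeq2 also brought its own size factors and filtering, so that 18718 genes were tested in its KO average. They were size factors of the DESeq2 type, total counts, no filter, a filter of 1 CPM in 3 libraries, DESeq2 1.42.0, a fit of only the groups compared, the replicate number as a block, a robust prior, an added threshold of 1 on the log2 scale, and the removal of each library in turn. Group labels were also redrawn, with 100 of the 840 distinct splits for results over all groups and all 10 splits for results on 2 groups.

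The steps were tested on simulated data with known changes made from the dispersion of these libraries. Only 200 genes, or 200 repeat subfamilies, were changed, as many up as down and alike in both KO groups. In the real KO average 71.2% of genes were called, and most transposable elements rose. Recovery, false calls and scaling were therefore not tested in a setting like that of the data. For the KO average, with 13733 genes, 58% of genes changed 1.2-fold, 79.6% of those changed 1.5-fold, 89.8% of those changed 2-fold and 100% of those changed 4-fold were recovered, and 15 unchanged genes were called. With no list changed, 1 of 31 lists was called. For repeats, with 977 subfamilies, recovery was 51% at 1.2-fold and 92% at 1.5-fold, and 14 unchanged subfamilies were called. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. Simple repeats were not tested, and copies of genes on the pseudoautosomal region of chromosome Y (45) were kept as separate features. Sequence reads, and with them the edited sites, splicing and single copies of repeats, were not analysed here. The level of 1 gene is not reported here.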

Results

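RNA was sequenced from MOLM-13 cells, an established human myeloid leukemia line that carried an inducible Cas9 nuclease. The cells had received either a control guide RNA or a guide RNA against MPHOSPH8 (MPP8), a chromodomain protein of the HUSH complex, which silences retroelements and other loci together with histone H3 lysine 9 methylation. The 9 libraries fall into 3 groups of 3, which are the control, KO-1 and KO-2. The stated purpose was to find which transcripts differ between control and MPHOSPH8 knockout cells. Counts assigned to genes totalled 14770649, 14867377 and 16567775 in the control libraries. They totalled 14982362, 15120067 and 10531040 in the libraries labelled KO-1 and 14945617, 14931647 and 13361977 in those labelled KO-2. Repeats took a further 7.84% to 8.03% of all counts in the control libraries, 10.35% to 10.6% in KO-1 and 9.48% to 9.72% in KO-2. After a filter on low counts, 13995 genes were tested. The correlation of log CPM was 0.992 to 0.994 within a group, 0.948 to 0.952 between control and KO-1, 0.964 to 0.968 between control and KO-2, and 0.977 to 0.978 between KO-1 and KO-2. The first principal component held 64.2% of the variance and separated the control from both KO groups, and the second held 19.7% and separated KO-1 from KO-2. The labels do not say that replicates came from separate cultures, so p-values measure only the spread between these libraries, which may be technical. No pair of replicates was within sampling noise, with chi-square values per degree of freedom of 1.27 to 3.85.

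MPHOSPH8 (ENSG00000196199.14), on chromosome 13 from 19633681 to 19673459 in the GRCh38 gene models, was not lower in the libraries labelled knockout. Its normalised level was 81.7 CPM ± 1.46 in the control, 129.5 ± 5.33 in KO-1 and 123.2 ± 1.77 in KO-2 (SD, n = 3 each). All 6 KO libraries lay above all 3 control libraries, and the log2 fold change of the KO average was 0.63 (SE 0.033, edgeR adjusted p = 3.86e-16). Cas9 cuts the gene and need not lower its transcript, so the level neither shows nor excludes a knockout. Every direction below therefore refers to the libraries labelled KO-1 and KO-2. The counts per gene hold no read sequence at the guide sites, and the edit itself was not analysed here. Of 15 measured HUSH members and partners, 5 rose and 6 fell in the KO average (camera adjusted p = 0.843), counting MPHOSPH8 itself. TRIM28, a corepressor that recruits SETDB1, fell from 617.6 CPM ± 5.78 to 419.1 ± 17.4 in KO-1 and 494.3 ± 4.66 in KO-2 (log2 fold change -0.44, SE 0.024, adjusted p = 7.07e-16). ATRX, a chromatin remodeller that deposits histone H3.3 with DAXX, rose by a log2 fold change of 0.43 (SE 0.031, adjusted p = 7.19e-13), and DAXX fell by 0.36 on the log2 scale (SE 0.058, adjusted p = 4.15e-06). CBX3 (0.25), PPHLN1 (0.25) and TASOR2 (0.23) also rose. SUV39H2 (-0.24), SUV39H1 (-0.23), TASOR (-0.09) and CBX5 (-0.07) fell, although TASOR and CBX5 lost the call under total-count scaling and without Control replicate 3. TASOR2 was called in KO-2 (0.44) and not in KO-1 (0.02, adjusted p = 0.566). In KO-2 the other 4 were not called, namely SUV39H2 (-0.04, adjusted p = 0.508), SUV39H1 (-0.10, 0.148), TASOR (-0.03, 0.42) and CBX5 (-0.05, 0.165). With both KO groups fitted as 1 group, the average lost the calls of TASOR2 (adjusted p = 0.121), SUV39H2 (0.159), SUV39H1 (0.0738), TASOR (0.223) and CBX5 (0.242). SETDB1, the methyltransferase of the complex, ATF7IP, CBX1 and MORC2 did not pass the test, with values of 0.01, -0.03, -0.01 and -0.10, and the signs of SETDB1, ATF7IP and CBX1 turned with the scaling or the filter. In single KO groups CBX1 was called in opposite directions, lower in KO-1 (-0.20, adjusted p = 1.03e-05) and higher in KO-2 (0.19, adjusted p = 2.45e-05). MORC2 (-0.20, adjusted p = 0.00137) and ATF7IP (-0.13, 0.0107) fell in KO-2, and SETDB1 rose in KO-1 (0.08, 0.0284).

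**Figure D1:**
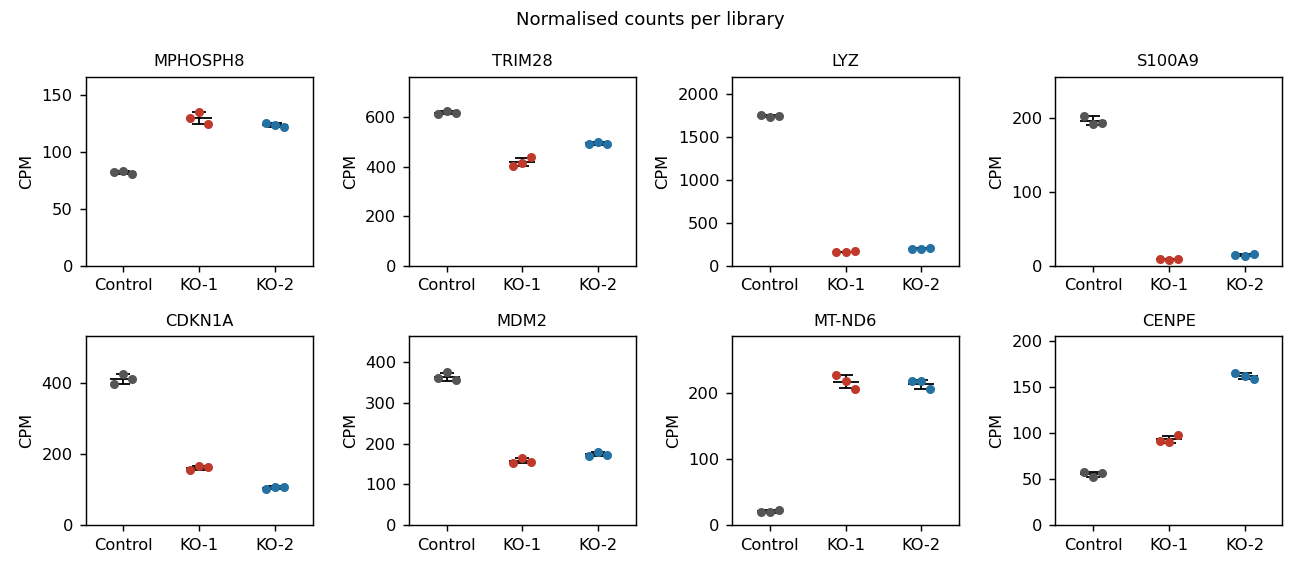
Normalised CPM (vertical axis from 0) of 8 named genes in each library, with the control, KO-1 and KO-2 groups along the horizontal axis. Points are the 3 libraries of a group, and the bar is their mean with its SD; MPHOSPH8 averages 81.7 CPM in the control and 129.5 and 123.2 CPM in the libraries labelled KO-1 and KO-2.

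The average of both KO groups was then compared with the control. A call in this average can come from 1 KO group alone. FOS, for example, was called raised at 1.43, with 3.84 in KO-1 and -0.97 in KO-2. Genes called in both KO groups are counted further below. Genes of monocytes were among the 10 most lowered genes named. LYZ, the secreted lysozyme of myeloid cells, fell from 1742 CPM ± 7.97 to 160.1 ± 3.62 in KO-1 and 198.2 ± 6.55 in KO-2 (log2 fold change -3.29, SE 0.022, adjusted p = 7.3e-38). S100A9 and S100A8, the calprotectin subunits, fell by 4.16 (SE 0.042) and 4 (SE 0.06) on the log2 scale. S100A9 went from 196.7 CPM ± 5.86 to 8.39 ± 0.555 and 14.5 ± 0.845, and S100A8 from 135.5 CPM ± 4.21 to 5.33 ± 0.913 and 13.2 ± 2.29. The other lowered genes named by rule were BHLHE22, a neuronal basic helix-loop-helix factor (-5.33), ADGRL3, an adhesion receptor (-4.87), MAN1A1, a Golgi mannosidase (-4.63), IKZF2, an Ikaros-family factor (-4.13), STON1 (-3.85), TENT5C (-3.48) and LAMC3, a laminin chain (-3.46). BHLHE22 had only 3 counts in KO-1 against 254 in the control, a ratio of 0.0129 (exact 95% counting interval 0.00265 to 0.0383). The raised genes were led by the mitochondrial tRNAs MT-TE (4.60), MT-TA (4.19), MT-TQ (3.95) and MT-TP (3.85), before NEIL1, a DNA glycosylase of base excision repair (3.59), and MT-ND6 (3.40). MT-ND6, a subunit of respiratory complex I, went from 20.4 CPM ± 1.76 to 217.5 ± 10.4 and 213.9 ± 6.94. HERC5, an interferon-induced ubiquitin-like ligase (3.11), ZFP3 (3.07), MEIOB, a meiotic recombination factor (3.03), and AMY2B, a pancreatic amylase (2.98), followed.

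In edgeR's quasi-likelihood test, 5048 genes rose and 4923 fell in the KO average, together 71.2% of the genes tested. Replicates varied by a biological coefficient of variation of 2.99%, so small changes passed, and the median size of a called change was 0.44 on the log2 scale. A test against a change of 1.5-fold, added after seeing the data, called 1666 genes raised and 747 lowered. Some mitochondrial genes have nuclear copies, and AMY2B has close paralogs, so reads of these genes could be split or shared in counting.

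Of 46 measured genes of monocyte and macrophage differentiation, 28 were tested. Of these, 22 fell and 4 rose in the KO average, with a median log2 fold change of -0.68 (camera adjusted p = 3.9e-21). The call held with an adjusted p = 0.00101 with an estimated correlation. The summed level of the list was 3742 CPM ± 11.7 in the control, 1665 ± 4.33 in KO-1 and 1564 ± 11.2 in KO-2 (SD, n = 3). LYZ, a member of the list, made up much of that fall, from 1742 CPM to 160.1 in KO-1 and 198.2 in KO-2. Of 20 genes of granulocyte differentiation, 15 fell and 3 rose (median -0.68, adjusted p = 1.63e-11; adjusted p = 0.0564 with an estimated correlation, where the call was lost). RNASE2, an eosinophil ribonuclease, fell by 1.66 on the log2 scale, from 972.9 CPM ± 20.6 to 237.9 ± 1.01 and 398.8 ± 3.28. PRTN3 and CTSG, serine proteases of azurophil granules, fell by 1.27 (SE 0.022) and 0.72 (SE 0.021). Of 16 antigen presentation genes, 12 fell and 4 rose (median -0.49, adjusted p = 0.00216; adjusted p = 0.0564 with an estimated correlation, where the call was lost). This list was called in KO-2 (median -0.79, adjusted p = 2.23e-06; adjusted p = 0.0089 with an estimated correlation) and not in KO-1 (-0.38, adjusted p = 0.145). The granulocyte list held in KO-2 as well (adjusted p = 0.00778 with an estimated correlation) and lost its call in KO-1 (adjusted p = 0.229 with an estimated correlation). HLA-B, a class I heavy chain, fell from 118 CPM ± 5.91 to 68.5 ± 1.10 and 44.8 ± 1.26. TAPBP, which loads peptides on class I molecules, fell by 1.08, and CD74, the class II invariant chain, by 0.66. HLA genes are polymorphic and similar to each other, which makes their counts uncertain.

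Targets of p53 were lower as a group. Of 34 tested targets, 29 fell and 3 rose, with a median log2 fold change of -0.70 (camera adjusted p = 1.28e-13; adjusted p = 0.00167 with an estimated correlation). CDKN1A, the p21 inhibitor of cyclin-dependent kinases, fell from 410.5 CPM ± 15.0 to 160.6 ± 5.38 in KO-1 and 105 ± 4.29 in KO-2 (log2 fold change -1.66, SE 0.029). MDM2, a ubiquitin ligase, fell from 364.9 CPM ± 9.57 to 158 ± 6.01 and 174.5 ± 5.15, and ZMAT3, an RNA-binding target, fell by 1.45 (SE 0.041). The median was -0.59 in KO-1 and -0.60 in KO-2.

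Genes of the integrated stress response, which act in amino acid supply and tRNA charging, rose. Of 33 tested, 30 rose and 0 fell in the edgeR test (median 0.33, camera adjusted p = 3.48e-08; adjusted p = 0.016 with an estimated correlation). The call came from KO-1 (31 rose and 1 fell, adjusted p = 7.69e-18; adjusted p = 0.00248 with an estimated correlation), and the list was not called in KO-2 (16 and 10, adjusted p = 0.362). STC2, a secreted glycoprotein, rose from 12 CPM ± 0.71 to 55.4 ± 2.89 in KO-1 and 25 ± 0.9 in KO-2. ALDH1L2, a mitochondrial folate enzyme, rose by 0.63 (SE 0.025), and PHGDH, the entry enzyme of serine synthesis, by 0.53 (SE 0.027). Of 24 genes of the unfolded protein response, 18 fell and 3 rose (median -0.43, adjusted p = 3.74e-09; adjusted p = 0.103 with an estimated correlation). HSPA5, the BiP chaperone of the endoplasmic reticulum, fell from 734.9 CPM ± 6.25 to 256.5 ± 4.33 and 558.6 ± 3.64. CALR, a lectin chaperone, fell by 0.80 (SE 0.018), and PDIA4, a disulfide isomerase, by 1.09 (SE 0.031).

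Genes of the cell cycle moved by less. Of 41 genes of G2 and mitosis, 27 rose and 6 fell in the KO average (median 0.18, camera adjusted p = 0.00279; adjusted p = 0.176 with an estimated correlation). CENPE, a kinetochore motor, went from 55 CPM ± 2.79 to 92.8 ± 3.98 and 161.8 ± 2.92, CENPF rose by 0.78 and MKI67, the proliferation antigen, by 0.37. MKI67 rose in KO-2 (0.69) and was not called in KO-1 (0.04, adjusted p = 0.125). With both KO groups fitted as 1 group, the calls of MKI67 (adjusted p = 0.0928) and of the G2 and mitosis list (0.135) were lost. Of 40 genes of DNA damage signalling and repair, 24 rose and 6 fell (median 0.15, adjusted p = 0.0101; adjusted p = 0.257 with an estimated correlation). That list was called in KO-2 (31 rose and 2 fell, median 0.26, adjusted p = 2.17e-06; adjusted p = 0.0778 with an estimated correlation) and not in KO-1 (15 and 12, median 0.00, adjusted p = 0.505). FANCA of the Fanconi pathway rose by 1.03 (SE 0.044) and the nuclease MRE11 by 0.75 (SE 0.039), while the histone H2AX fell by 0.67 (SE 0.034). Of 18 CDK inhibitors and genes of cell cycle exit, 10 fell and 5 rose (median -0.20, adjusted p = 0.0466; adjusted p = 0.167 with an estimated correlation). That call was also lost under total-count scaling (adjusted p = 0.0608), with the 1 CPM filter (0.0581), without KO-1 replicate 3 (0.0504), without KO-2 replicate 2 (0.0509) and with both KO groups fitted as 1 group (0.334). BTG2, an antiproliferative factor, fell from 35 CPM ± 0.874 to 21.9 ± 1.84 and 7.03 ± 0.856, while RBL2, a pocket protein, rose by 0.43 (SE 0.029). The list median was 0.32 in KO-1 (not called, adjusted p = 0.505) and -0.50 in KO-2, so the average joins opposite signs. The list of G1 and S phase was not called (15 rose, 18 fell of 40, adjusted p = 0.897), although HELLS (0.72), RFC4 (0.69) and PCNA (0.46) rose. The list of the MLL-fusion and leukemia stem cell programme was not called either (15 rose, 11 fell of 34, adjusted p = 0.662). In it LAPTM4B (-0.63) and RUNX1 (-0.42) fell and JMJD1C (0.41) rose.

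Among non-coding and repetitive gene families, 36 of 2683 measured small nucleolar and small nuclear RNAs passed the filter. Of these, 31 rose and 1 fell (median 1.54, camera adjusted p = 0.0118, and 0.216 with an estimated correlation). Members with few counts in the control can pass the filter through the KO groups alone. The share raised therefore holds only for those tested. SNORD104 went from 1.28 CPM ± 0.225 to 6.06 ± 0.165 and 6.02 ± 0.472, SNORA33 rose by 1.53 (SE 0.156) and SNORA73B by 1.09 (SE 0.15). Of 400 numbered zinc finger genes, many of which encode repressors bound to transposable elements, 195 rose and 75 fell (median 0.19, adjusted p = 0.0033; adjusted p = 0.0564 with an estimated correlation, where the call was lost). After the trend of fold change on GC content and transcript length was removed, the zinc finger median was 0.09 (preranked camera p = 0.0335, unadjusted, n = 400 genes). ZNF117 went from 52.7 CPM ± 0.662 to 257.9 ± 5.56 and 116.7 ± 2.89, ZNF731P rose by 1.51 and ZNF692 by 1.47. ZNF731P is annotated as a pseudogene, and zinc finger genes are similar to each other, so their counts are uncertain. Of 13 mitochondrially encoded mRNAs, 8 rose and 2 fell (median 0.16, adjusted p = 0.000312; adjusted p = 0.276 with an estimated correlation). They were called in KO-2 (10 rose and 1 fell, median 0.24, adjusted p = 8.88e-09; adjusted p = 0.111 with an estimated correlation, where the call was lost) and not in KO-1 (6 and 5, median 0.01, adjusted p = 0.102). Besides MT-ND6, MT-ATP8 (0.47, SE 0.024) and MT-ND1 (0.39, SE 0.02) rose. The mitochondrial genome took 3.72% ± 0.130 of gene counts in the control, 4.37% ± 0.0540 in KO-1 and 4.49% ± 0.0995 in KO-2.

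The list of the type I interferon response was not called (14 rose and 14 fell of 45, camera adjusted p = 0.662). TRIM22 fell by 1.24 (SE 0.033) and BST2, which tethers virus particles, by 0.93 (SE 0.042), while XAF1 rose by 0.58 (SE 0.035) and HERC5 rose as above. Nucleic acid sensors (6 rose and 7 fell of 15, adjusted p = 0.206), LINE-1 restriction factors (7 and 8 of 22, 0.113) and the inflammatory NF-kB response (2 and 10 of 19, 0.283) were not called. Replication-dependent histones were not called (0 rose and 14 fell of 19, median -0.93, adjusted p = 0.141 by camera). That does not show that the histones were unchanged. Retroelement-derived and imprinted genes (8 and 4 of 13, 0.13) were not called either. The same held for MYC targets (13 and 16 of 42, 0.694), apoptosis regulators (7 and 14 of 29, 0.577), cholesterol synthesis (5 and 10 of 23, 0.206) and glycolysis and hypoxia (10 and 14 of 29, 0.18). It held for cytosolic ribosomal proteins (41 and 22 of 79, 0.206) and clustered protocadherins (1 and 1 of 8, 0.897) as well. Some of these lists were called in a single KO group with the preset correlation, and each of those calls was lost with an estimated one. MYC targets were lower in KO-1 (adjusted p = 0.0299) and higher in KO-2 (0.0362), and ribosomal proteins were higher in KO-1 (60 of 79, 0.000606). In KO-2 histones (0.0289), nucleic acid sensors (0.0224) and megakaryocyte markers (0.0373) were lower, and G1 and S phase genes (0.0289) higher. Median, mean and test differed in sign for the HUSH, LINE-1 restriction, interferon, nucleic acid sensor, G1 and S phase, MYC, megakaryocyte and apoptosis lists, none of which was called. In all, 12 of 31 tested lists were called with the preset correlation, and monocyte differentiation, p53 targets and the integrated stress response held with an estimated one. Adjusted over the list alone, the counts of raised and lowered members matched those over all genes for every list but 6. These were the interferon (13 and 14), DNA repair (25 and 6), G1 and S phase (16 and 18), cholesterol (5 and 9), zinc finger (193 and 73) and small RNA (32 and 1) lists.

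**Figure D2:**
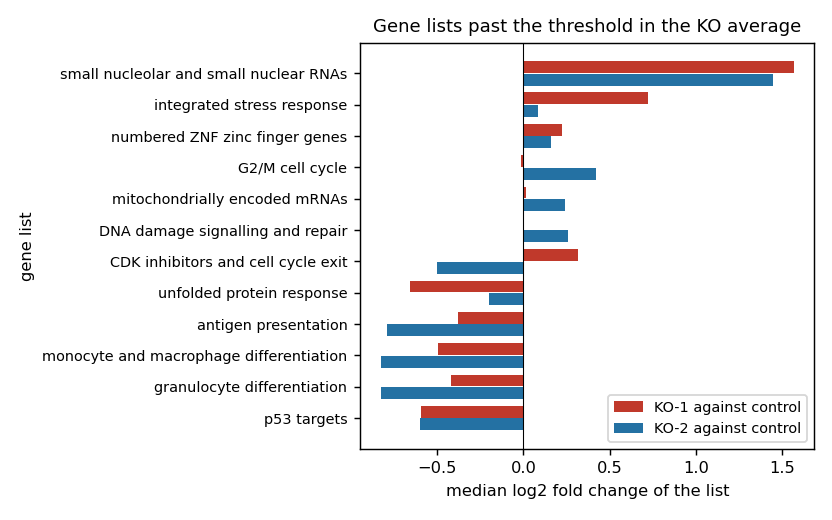
Median log2 fold change (horizontal axis) of the 12 gene lists (vertical axis) called in the KO average, with a bar for KO-1 and a bar for KO-2 against the control. The p53 list lies at -0.59 and -0.60, and the G2 and mitosis list at -0.01 in KO-1 and 0.42 in KO-2.

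Summed levels of markers of other blood and tissue cells differed in both directions. Erythroid markers summed to 482.7 CPM ± 9.21 in the control, 334 ± 11.6 in KO-1 and 479.3 ± 9.49 in KO-2. Megakaryocyte markers summed to 311.3 ± 7.53, 387.9 ± 7.61 and 250.5 ± 6.03, and T and NK cell markers to 178.7 ± 5.84, 184.8 ± 4.22 and 168.9 ± 2.75. B cell markers, with 3 genes passing the filter and no list test, summed to 87.8 ± 4.72, 114.5 ± 3.37 and 84.5 ± 2.93. Epithelial and stromal markers summed to 79.6 ± 5.47, 68.9 ± 5.30 and 51.6 ± 1.14. None of the erythroid (adjusted p = 0.976), megakaryocyte (0.538), T and NK cell (0.116) and epithelial and stromal lists (0.267), with 5 tested genes each, was called in the KO average. Cancer-testis and germline genes, of which 4 passed the filter, summed to 121.9 CPM ± 6.01, 148.7 ± 2.66 and 180.9 ± 3.96.

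Each KO group was next compared with the control alone, to see what the groups have in common. In KO-1, 5202 genes rose and 5082 fell, and in KO-2, 4868 rose and 4155 fell. Both groups shared 3435 raised and 2965 lowered genes, where independent lists of these sizes would share 1809 and 1509. A further 963 genes moved in opposite directions. Beyond 1.5-fold, 1008 genes rose and 372 fell in both, and 10 went in opposite directions. Among genes changed the same way, 69% had the larger change in KO-1, and the median ratio of the KO-2 to the KO-1 log2 fold change was 0.796. LYZ fell by 3.44 in KO-1 and by 3.14 in KO-2, and MT-ND6 rose by 3.41 and 3.39. Across genes, which are not independent replicates, the log2 fold changes of the groups correlated with r = 0.792. Both share the same control libraries, and 100 simulated pairs of unchanged groups against those controls gave a mean r of 0.036 and a highest of 0.0679, computed on log CPM, where the observed r was 0.78. These pairs were drawn around the mean of the same controls, which removes the sampling error that shared controls add. Their low r was therefore built in and does not measure what shared controls give. The covariance was 0.408 against 0.000561 in the simulations, a difference of 0.408, and 75.2% of genes had the same sign against 50.4%. With 3 controls no split into groups of at least 2 was possible, so part of the correlation and of the excess in overlap may come from the shared controls.

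The groups were also compared with each other. The 5 lowest genes in KO-2 relative to KO-1 by the naming rule are immediate-early genes, which are induced within minutes of a stimulus. FOS averaged 18.4 CPM ± 0.672 in the control, 262.3 ± 8.18 in KO-1 and 9.36 ± 0.925 in KO-2 (KO-2 minus KO-1 log2 fold change -4.81, SE 0.054, adjusted p = 1.03e-31). FOSB (-5.72), DUSP1 (-3.93), EGR1 (-3.84) and JUN (-3.16) went the same way, with the control between the KO groups for each. NQO1, a quinone reductase, averaged 31.6 CPM ± 0.896, 9.97 ± 0.754 and 62.5 ± 1.83 (2.65, SE 0.068), and PIR, an iron-binding nuclear protein, was higher in KO-2 by 2.25 (SE 0.149). MMP2, a gelatinase (2.48), EPHB2, an ephrin receptor (2.34), and FAM124A (2.06) were also higher in KO-2. In edgeR's test, 4205 genes were higher and 4076 lower in KO-2 than in KO-1, and 256 and 692 beyond 1.5-fold.

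As groups, 38 of 41 genes of G2 and mitosis were higher in KO-2 than in KO-1 and 0 lower (median 0.44, camera adjusted p = 3.51e-23; adjusted p = 0.00456 with an estimated correlation). Adjusted over the list alone, 39 were higher. Against the control, 40 of them rose in KO-2 (adjusted p = 0.00778 with an estimated correlation), and 13 rose and 17 fell in KO-1, where the list was not called (adjusted p = 0.561). Of 18 CDK inhibitors and genes of cell cycle exit, 15 were lower and 1 higher in KO-2 (median -0.52, adjusted p = 0.00456 with an estimated correlation). Of 33 genes of the integrated stress response, 30 were lower and 1 higher in KO-2 (median -0.53, adjusted p = 0.000431 with an estimated correlation). Adjusted over the list alone, the counts of these 2 lists were the same. Against the control, that stress list had a median of 0.72 in KO-1 and 0.09 in KO-2. The unfolded protein response was higher in KO-2 than in KO-1 (15 of 24, median 0.54, camera adjusted p = 6.31e-13; adjusted p = 0.0685 with an estimated correlation). The MYC target list (33 of 42 higher in KO-2, median 0.25) had an adjusted p = 0.113 with an estimated correlation, and cytosolic ribosomal proteins (72 of 79 lower, median -0.28) had an adjusted p = 0.334 with an estimated correlation.

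**Figure D3:**
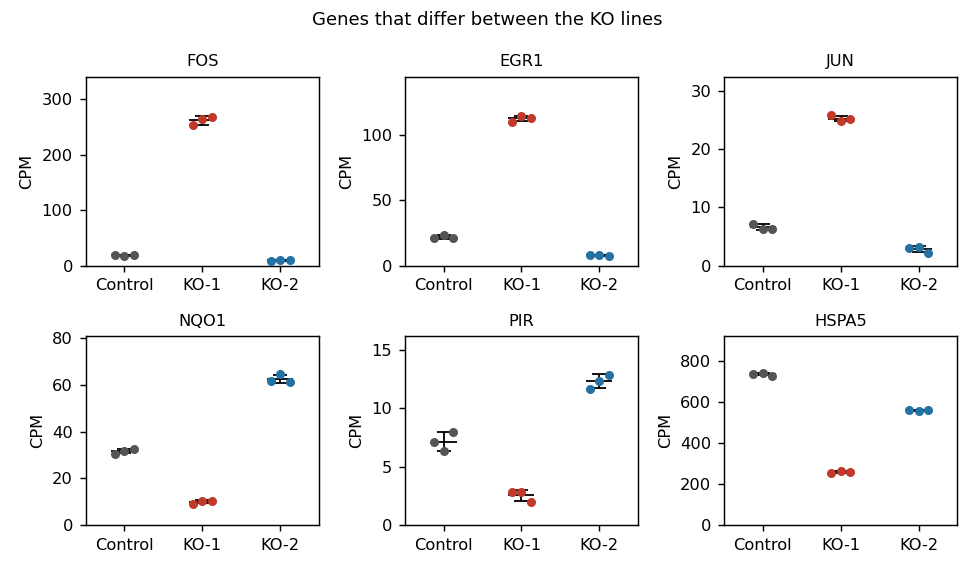
Normalised CPM (vertical axis from 0) in each library for 6 genes that differ between KO-1 and KO-2, with groups along the horizontal axis; points are the 3 libraries and the bar is the mean with its SD. FOS averages 262.3 CPM in KO-1 and 9.36 in KO-2, and NQO1 9.97 and 62.5.

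HUSH is known to act on retroelements and on long transcripts without introns, so the structure of the changed genes was compared. Of 1487 tested genes with a single exon, 23.9% rose in both KO groups, against 24.6% of genes with more exons (odds ratio 0.967, 95% interval 0.85 to 1.10, Fisher's exact two-sided adjusted p = 0.632). The odds ratio passed the threshold below 1 with several other processing choices and lay at 1.04 in another. Single-exon genes were more frequent among genes lowered in both (odds ratio 1.61, adjusted p = 9.6e-14). Among protein-coding genes, the 188 with a single exon were under-represented among raised genes (14.9% against 22.6%, odds ratio 0.598, adjusted p = 0.0129) and over-represented among lowered genes (odds ratio 1.79, adjusted p = 0.000476). Long non-coding RNA genes were over-represented among raised genes (41.6% of 1451 against 22.5% of other genes, odds ratio 2.45, adjusted p = 3.22e-51). Pseudogenes other than processed ones rose more often too (54.1% of 255, odds ratio 3.75). Genomic DNA and reads counted on the wrong strand, left open below for other patterns, were not tested as sources of these rises. Processed pseudogenes, which are retrocopies of mRNAs, fell more often (46% of 802, odds ratio 3.46), and their summed level was 20900 CPM ± 3325 in the control, 16500 ± 1464 in KO-1 and 14710 ± 1524 in KO-2. Only 7.23% of processed pseudogenes rose in both KO groups, against 25.5% of other genes. Reads of processed pseudogenes can be shared with their parent genes. The comparison of all single-exon genes pooled every class and was not run without processed pseudogenes, so its odds ratios depend on the mix of classes. Chromosome 19, which holds many zinc finger genes, was not over-represented among raised genes (odds ratio 0.947, adjusted p = 0.546).

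Counts for repeat subfamilies came with the gene counts, and their analysis was chosen after seeing the data. L1HS and L1PA2, evolutionarily young members of the LINE family that holds the active human retrotransposons, rose most among well-counted subfamilies. L1HS, the human-specific subfamily, averaged 16.2 CPM ± 1.25 in the control, 122.4 ± 12.1 in KO-1 and 95.8 ± 12.4 in KO-2 (log2 fold change of the KO average 2.73, SE 0.069, adjusted p = 5.7e-37). L1PA2 went from 45.9 CPM ± 1.91 to 323.2 ± 36.3 and 251.1 ± 17.5 (2.63, SE 0.051). L1PA3 rose by 2.13 (SE 0.038) and L1PA4 by 1.78 (SE 0.037). These are normalised to gene counts, and all 6 KO libraries lay above all 3 control libraries for each. L1HS and L1PA2 ranked 1 and 2 of 683 transposable element subfamilies at 3 CPM or more, and 3 and 5 of 918 without that minimum. As a family the 127 L1 subfamilies exceeded other transposable elements (camera p = 3.41e-39; p = 0.00119 with an estimated correlation), and so did the 48 Alu subfamilies (p = 1.43e-10; p = 0.0259 with an estimated correlation). The median of the 4 subfamilies was 2.38, and that of the older L1PA5 to L1PA17 was 1.42, L1MA 1.28, L1MB 1.09, L1MC 1.03, L1MD 0.95 and L1ME 1.18. The 4 were grouped after their values were seen, so a test of that group against the other subfamilies is circular and is not given.

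Relative to gene counts, 806 of 918 transposable element subfamilies rose and 20 fell in the KO average. When the repeats were scaled by factors of their own, 279 of 911 rose and 284 fell. Such factors set the typical subfamily near 0, so this near-equal split was built in and does not speak against a general rise. L1HS still rose by 1.86 and L1PA2 by 1.76 under that scaling. Relative to gene counts, the 127 L1 subfamilies had a median of 1.21 and all 48 Alu subfamilies rose (median 0.97). So did 28 of 31 ERVK (1.17), 195 of 243 ERV1 (0.84) and 6 of 6 SVA subfamilies (0.44). In KO-2, 151 ERV1 subfamilies rose and 13 fell, and 4 of 6 SVA subfamilies rose (median 0.26). Of 216 DNA transposon subfamilies, 192 rose and 2 fell in the KO average (median 0.86). All 5 MIR (0.575) and 7 of 8 L2 subfamilies (0.64) rose. Summed DNA transposons were 1.71-fold the control in KO-1 and 1.485-fold in KO-2. MIR was 1.78-fold and 1.515-fold, L2 1.75-fold and 1.45-fold, Alu 1.98-fold and 1.73-fold, and L1 2.498-fold and 2.119-fold. Transposable elements together reached 41580 CPM, relative to gene counts, ± 1125 in the control, 80080 ± 1411 in KO-1 and 68700 ± 1169 in KO-2, which are 1.93-fold and 1.65-fold the control. KO-2 lay below KO-1 for 532 subfamilies and above it for 16. HERVH-int, the internal part of an endogenous retrovirus, averaged 44.1 CPM ± 0.842 in the control, 140.1 ± 2.25 in KO-1 and 54.2 ± 2.55 in KO-2. Subfamilies share reads, and how reads that map to several places were assigned to them is not given in the sources used here. The subfamily counts therefore do not say which genomic copies gave the reads.

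**Figure D4:**
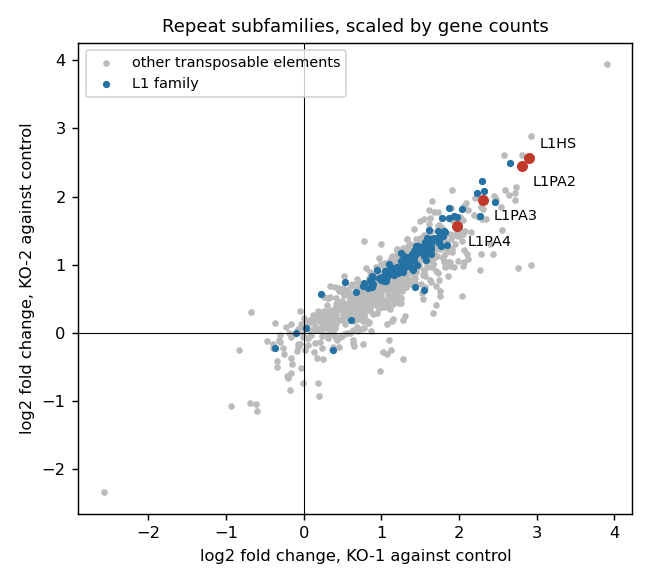
Log2 fold change of each transposable element subfamily in KO-1 (horizontal axis) and KO-2 (vertical axis) against the control, normalised to gene counts. Gray points are other subfamilies, blue points the L1 family and red points L1HS and L1PA2 to L1PA4; L1HS lies at 2.90 and 2.56, and with factors taken from the repeats 284 subfamilies fell and 279 rose.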

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

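The tests of an equal rise of all transposable elements, of genomic DNA and of mitochondrial tRNAs were chosen after the result was seen, as was the 1.5-fold basis of the differences between KO-1 and KO-2 given here. The other tests had their predictions written first.

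Genes named in the report were singled out where KO-2 and KO-1 differed by more than 1.5-fold, tested on the KO-2 minus KO-1 log2 fold change. The immediate-early genes FOSB (-5.72), FOS (-4.81), DUSP1 (-3.93), EGR1 (-3.84) and JUN (-3.16) were lower in KO-2. So were NEIL1 (-1.44), AMY2B (-1.32), LAMC3 (-1.96), BTG2 (-1.65), STC2 (-1.15) and ZNF117 (-1.15). NQO1 (2.65), MMP2 (2.48), EPHB2 (2.34), PIR (2.25) and FAM124A (2.06) were higher in KO-2. The chaperone genes HSPA5 (1.12), CALR (0.92) and PDIA4 (1.13) and the mitotic genes CENPF (0.66), CENPE (0.81) and MKI67 (0.65) were higher as well. So were S100A8 (1.30), RNASE2 (0.75), BST2 (0.84) and LAPTM4B (0.66). As groups, genes of G2 and mitosis were higher in KO-2 (median 0.44), and CDK inhibitors (-0.52) and the integrated stress response (-0.53) lower. The endogenous retrovirus HERVH-int was lower in KO-2 (-1.37).

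The young subfamilies L1HS and L1PA2 to L1PA4 rose more than most other transposable elements, and a rise of all subfamilies in equal proportion is excluded, since with factors taken from the repeats the median element was at 0.04 while the lowest of the 4 was at 0.90 (SE 0.035; largest edgeR adjusted p of the 4 over 981 subfamilies = 1.04e-19). For the rise of the L1 family, which holds about 17% of the genome by general knowledge, genomic DNA was bounded from 861 olfactory receptor genes. These lay at 2.64 CPM per Mb in the control, 6.13 in KO-1 and 3.66 in KO-2. By the upper bound, the L1 family would need 37.6% of DNA reads in KO-1 and 66.8% in KO-2. That argues against DNA as the whole cause only if reads that map to several places were counted alike on genes and repeats. How they were counted is not given, so DNA is not excluded for the family. The planned comparison had let the DNA reads of the whole genome fall on L1, up to 2.66 times its gain, and so decided nothing. For the 4 subfamilies DNA could not be excluded either, since they would need 4.05% and 6.83%. Neither their share of the genome nor the counting of reads that map to several places is given in the sources used here. Alpha satellite was not called in KO-2 (23.4 CPM against 22.5) but was higher in KO-1. Satellite repeats together were 1.74-fold the control in KO-1 and 1.10-fold in KO-2. Loss of HUSH silencing, the biology the design names, remains possible, but the pattern is not called biological, because DNA stays open. Other sources of the repeat reads were not tested. MPHOSPH8 mRNA was higher in the libraries labelled knockout, which does not tell whether the protein was lost.

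Mitochondrial genes of the light strand rose, MT-ND6 by 3.40 and 7 tRNAs by a mean of 3.83. A general rise of mitochondrial RNA without poly(A) tails could not be excluded: without the 4 light-strand tRNAs that prompted the test, the other 3 rose by 1.88 more than the 10 of the heavy strand, which rose by a mean of 1.53 (exact permutation p = 0.101), and MT-TG of the heavy strand rose by 6.84. Apart from MT-TG, the heavy-strand tRNAs lay between 0.46 and 1.63, below the lowest light-strand tRNA (2.78). Heavy-strand reads counted on the wrong strand could not be excluded either, since 31 nuclear genes inside exons of a well-expressed opposite-strand gene had a median of 1.17, with a 90th percentile of 2.09. No biological explanation was tested.

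Targets of p53 fell in the KO libraries. The scaling of the libraries is excluded, since the list median was 10.1 times the largest shift of the median of all genes between scalings (0.07). GC content and transcript length are excluded, since the median was -0.77 after their trend was removed and -0.70 before (preranked camera p = 1.02e-08 after, n = 34 genes). The knockout, and a difference in culture between the groups, could each account for this, and nothing in the labels separates them.

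Group labels were redrawn to see how often chance gives results as large. For genes changed in the KO average the real grouping was the only 1 of 100 splits with as many calls, and the highest other split gave 2288. The same held for genes changed in both KO groups (1 of 100, highest other 602) and for transposable elements (1 of 100, highest other 632). Other splits mostly mix control and KO libraries within a group, which puts their differences into the error and lowers the calls. The real grouping was therefore favoured in advance, and these counts do not exclude chance. For the number of gene lists called, 32 of 100 splits reached the real value of 12 (highest other 19), so these splits do not exclude chance. For the correlation of the KO groups, 0.792, 31 of 100 did (highest other 0.892), so they do not exclude it there either. Because of that mixing, the lists and correlations of these splits are not those of unchanged groups either. In simulations 1 of 31 lists was called with no list changed. The simulated correlation of unchanged groups, at most 0.0679 against 0.78 observed, leaves out the error of the shared controls and decides nothing here. For KO-1, KO-2 and KO-2 against KO-1 only 10 splits exist, in which the real one was the 1 with the most calls. Of the other 9 each gave 0 calls in edgeR, with 63 to 245 genes at unadjusted p under 0.05 for KO-1, 117 to 431 for KO-2 and 129 to 229 for KO-2 against KO-1. Those 10 splits are too few to exclude chance.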

How the results depend on the processing

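The tests here were fixed in advance, except glmTreat, the removal of processed pseudogenes and the alternatives for repeats, which were chosen after the data were seen. Each of 12 main results was compared in each setting that applied to it. The result was kept in 208 of these comparisons. Kept means within 1.5 times for a count, and the same direction and side of the threshold for a tested value. For the correlation it means above the highest simulated r of 0.0679. That value was built in, so the correlation could hardly fail. The result moved by over 1.5 times in 13, passed the threshold in 5 where it had not, and reversed in 1. The number of genes changed in the KO average (9971) was 6487 when both KO groups were treated as 1 group of 6, whose construction puts their differences into the error. With a log2 fold change of at least 1 it was 2063, and for KO-1, KO-2 and KO-2 against KO-1 it was 2608, 1809 and 884, and 1367 in both KO groups, since that threshold asks for more. Against a 1.5-fold change the counts were 2413, 3243, 1852, 948 and 1380 in the same order. Without processed pseudogenes they were 9598, 9867, 8718, 8214 and 6178 in the KO average, KO-1, KO-2, KO-2 against KO-1 and both. DESeq2 values come from several choices at once. Called lists numbered 12, but 3 with an estimated correlation and 26 with fry, which asks a different question. Lists not called in the report were called without a filter for histones (adjusted p = 0.00613), glycolysis (0.0434), cholesterol (0.00797) and MYC (0.0399), with DESeq2 for glycolysis (0.0066) and LINE-1 restriction (0.0434), with only the groups compared for histones (0.00916), and without Control replicate 1 for ribosomal proteins (0.0375). The odds ratio of single-exon genes among raised genes (0.967) was 1.04 with DESeq2-type size factors, 0.861 with total counts, 0.464 without a filter, 0.599 with DESeq2, 0.847 with only the groups compared, and 0.834 to 0.960 with a library left out (lowest without Control replicate 1, Fisher's exact p = 0.00544), and the cause was not tested.

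Leaving out each library in turn gave 9402 to 9963 genes in the KO average, 9838 to 10456 for KO-1, 8351 to 9077 for KO-2, 5884 to 6258 in both, and 7619 to 8501 for KO-2 against KO-1. It gave 11 to 13 lists, 801 to 830 transposable elements, a correlation of 0.775 to 0.802, MPHOSPH8 at 0.61 to 0.64 and L1HS at 2.67 to 2.78. Calls in the KO average were lost for EPHB2 without Control replicate 2 (adjusted p = 0.0565), Control replicate 3 (0.0553) or KO-1 replicate 1 (0.087), and for CBX5 (0.0938), TASOR (0.0576) and PIR (0.108) without Control replicate 3. MORC2 gained a call without Control replicate 2 (0.0384), KO-1 replicate 1 (0.0238) or KO-2 replicate 3 (0.0256), and with DESeq2-type size factors (0.0207) or no filter (0.00264).

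Values that changed sign all lie near 0 or differ between the KO groups, and the cause was not tested. With DESeq2-type size factors these were SETDB1 (-0.009) and the interferon and nucleic acid sensor lists (both 0). With total counts they were CBX1 (0.04), ATF7IP (0.02) and the HUSH (0.02), G1 and S phase (0.032) and MYC (0.038) lists. Without a filter they were SETDB1 (-0.044) and the LINE-1 restriction (-0.016), interferon (-0.026), sensor (-0.11), MLL (-0.012) and protocadherin (-0.20) lists. With at least 1 CPM they were CBX1 (0.002) and the sensor list (-0.042). With DESeq2 they were SETDB1 (-0.022) and the LINE-1 restriction (-0.032), interferon (-0.003), sensor (-0.087), erythroid (0.029) and protocadherin (-0.18) lists. With only the groups compared they were CBX1 (0.007), NQO1 (0.20) and PIR (0.064). With a library left out, SETDB1 ranged from -0.006 to 0.018 and the lists of LINE-1 restriction from -0.005 to 0.048, interferon from -0.021 to 0.067, and sensors from -0.022 to 0.039, all lowest without Control replicate 2. The G1 and S phase list ranged from -0.064 to 0.009, highest without Control replicate 1, and the protocadherin list from -0.34 to 0.19, lowest without KO-2 replicate 2.

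The labels give the groups the same replicate numbers. With the replicate block the counts were 10186, 10473, 9305, 8544 and 6624 genes in the KO average, KO-1, KO-2, KO-2 against KO-1 and both, with 13 lists and 826 transposable elements. Calls gained with the replicate block were ribosomal proteins (adjusted p = 0.0307) and MORC2 (0.0424). MPHOSPH8 was at 0.63, L1HS at 2.73, L1PA2 at 2.63, the correlation at 0.791 and the single-exon odds ratio at 0.973. Whether the numbers pair the libraries is not settled. Of 9 same-number correlations 0 exceeded 0.1, but they ran from 0 to 0.078, against -0.068 to 0.044 for other numbers. Of 18 best matches, each of a library with another group, 12 had the same number, which is only a hint of pairing from the data. No scaling moved the share of raised genes by over 10 percentage points. For transposable elements scaled by their own factors it did, as the report gives. Depth was lowest in KO-1 replicate 3, at 10531040 gene counts, which limits genes with few reads there.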

Other observations

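The tests of the immediate-early and NRF2 lists were chosen after the result was seen, and their members leave out the genes whose values prompted them.

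Repeats that are not transposable elements were not compared in the report. Ribosomal RNA sequences fell: the large-subunit repeat averaged 11720 CPM ± 282 in the control, 7686 ± 84.3 in KO-1 and 8013 ± 122.3 in KO-2 (SD, n = 3; log2 fold change of the KO average -0.58), and the small-subunit repeat 6719 ± 267.4, 3351 ± 59.9 and 3801 ± 110.1 (-0.91). The signal recognition particle RNA 7SLRNA rose by 0.41, from 67 CPM ± 5.38 to 99.4 ± 3.49 and 79.3 ± 3.35. Alpha satellite, the repeat of centromeres, averaged 22.5 CPM ± 0.515 in the control, 46.2 ± 1.00 in KO-1 and 23.4 ± 1.22 in KO-2. Simple repeats together took 18840 CPM, relative to gene counts, ± 473.7, 18360 ± 537.1 and 17520 ± 464.3. The mitochondrial ribosomal RNAs MT-RNR1 and MT-RNR2 rose by 0.61 each on the log2 scale.

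Immediate-early genes may differ between KO-1 and KO-2 as a group. Among 16 tested members, without the genes that prompted the test, 12 were lower and 1 higher in KO-2. Their median was -1.04 (preranked camera p = 8.62e-09, n = 16 genes). ATF3 and KLF6 among them also belong to the stress response and cell cycle exit lists, already found lower in KO-2. EGR3 (-5.27), EGR2 (-3.86), KLF2 (-2.04), ZFP36 (-1.97) and IER2 (-1.79) were lowest, and DUSP5 was higher (0.47). The result is consistent with a difference in signalling or in handling at harvest, and the labels do not say whether KO-1 and KO-2 differ by guide RNA or by clone, so these are not separated.

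Targets of the oxidative stress factor NRF2 may likewise differ. Among 16 tested members, without the genes that prompted the test, 14 were higher and 0 lower in KO-2 than in KO-1 by edgeR. Their median was 0.67 (preranked camera p = 1.72e-09, n = 16 genes). SLC7A11 among them also belongs to the integrated stress response list compared above. PRDX1 (0.98), FTL (0.82), TXNRD1 (0.81) and TALDO1 (0.77) were among them. Most lay below the control in KO-1, such as FTL (-1.17), TALDO1 (-0.93) and PRDX1 (-0.82), so the test indicates that lower levels in KO-1 could account for much of the difference. Whether this follows from the guide RNA, a clone or culture was not tested.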
